A study of Homo sapiens with 2 samples.

How the data were processed

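Total RNA of p62-knockdown and control U937 cells, 1 sample each, was digested with RNase R, amplified with random primers and labelled with Cy3, per the labels' protocols, and hybridised to a human circRNA array. The deposited scanner files give the intensity of 15603 spots per array from Agilent Feature Extraction 11.0.1.1, per the file headers; the processed signal is background-subtracted and spatially detrended within an array but not scaled between arrays. The deposited value table holds log2 values; limma is named in the submitters' processing notes, with no role given. Normexp background correction with an offset of 16 on the median spot and local background intensities, quantile normalization over all spots and log2 rebuilt the table to within 4.99e-09, so its scale is log2, it is not centred, and its direction follows the signal. Its column medians were 6.14 for the knockdown and 6.13 for the control.

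The main value was the log2 of the processed signal minus each array's 75th percentile over circRNA probes, and the comparison was the knockdown minus the control. A circRNA probe was compared if it was well above background on both arrays and not marked as an outlier, which left 12307. Outlier marks removed 9 circRNA spots on the knockdown array and 32 on the control array, and no circRNA spot was saturated. With 1 array per group no test between groups was run. The scanner error quoted is the scanner software's own error model and covers neither RNA preparation nor culture. R 4.3.3 with limma 3.58.1, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.

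The circRNA probes named in the report were chosen by rules set before the data were examined: the 12 highest and 12 lowest circRNAs, the largest bounds among circRNAs above background on 1 array, and the 6 brightest. Because the files do not pair circRNA probes with genes, at most 2 probe names each way are printed, and the parts of the rules that need host genes, classes or chromosomes were not analysed here, including SQSTM1 and the host-gene medians of the 18 lists. The accessions of all 70 mRNA probes were matched to symbols through a RefSeq table of GRCh38.p14, which was used for names only; the result of 1 of these probes is not reported here, though it is counted in the totals.

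Several choices were made after the data had been seen. The mRNA and control probes named in the text were picked after their values were seen, apart from the 7 genes of the fixed lists. The panels of mRNA, circRNA control and negative control probes were not part of the planned design. Their 10 spots were averaged without outlier spots, and a probe was called measured with at least 8 unflagged spots well above background on each array. A looser rule, at least 5 unflagged spots with 80% above background, was tried after the results of the first rule were known; it is reported only as an alternative. The negative control probe discussed in the closing section has 7 unflagged spots, fails the rule of 8, and was singled out after its values were seen. The list of 19 replication and mitosis genes was also drawn up after the panel was seen. Spots of a probe are technical replicates within 1 array, so an SE over spots does not describe the condition, and leaving out outlier spots narrows it. The scanner's population outlier mark is given to replicated probes only, and no circRNA spot carried it; the spot noise set against the circRNAs therefore keeps such spots, 103 of 1128.

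For the circRNA counts 16 alternatives were run, 13 set before the data were examined and 3 added afterwards. The files used here hold no mean spot signal, so the planned normexp correction was run on the median signal and counts among those added. To place a list, its median was ranked among 10000 random lists of the same size matched on level in 10 bins. Both steps were tested on simulated data. Of 100 circRNAs given a 3-fold change on arrays with spot noise only, 100 were counted at 2-fold, of 100 given 1.5-fold 1 was, and of 12107 left alone 30 were. The separate noise simulation of the closing section counted fewer, at most 23, and why the counts differ was not examined. Of 40 random lists 1 fell outside the central 95%, and of 40 lists shifted by 0.3 on the log2 scale 40 did.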

Results

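Circular RNAs were profiled in U937 cells, an established human monocytic leukaemia line, with a 1-colour circRNA microarray. The question was which circRNAs differ once p62, the autophagy receptor encoded by SQSTM1, is knocked down by lentiviral RNA interference. There was 1 array of p62-knockdown cells and 1 array of control cells. The differences below therefore have no replicate check, and no p-value was computed. A difference was counted by a fixed size rule of at least 2-fold. Each array held 13617 circRNA probes with 1 spot each, of which 12552 (92.2%) on the knockdown array and 12509 (91.9%) on the control array were well above background. The control array was brighter, with a 75th percentile of 186 intensity units against 133, a 1.40-fold difference that was scaled out. Both arrays came from the same slide and scan, and the position on the slide and the group cannot be told apart. Precision is limited by the number of arrays.

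The knockdown of SQSTM1 itself was not analysed here, because the files do not pair circRNA probes with host genes and SQSTM1 was not among the genes with an mRNA probe. The labels say that an empty vector was made, but call the second sample only a control, so whether it carried that vector is not known.

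Most circRNAs had closely similar levels in p62-knockdown and control cells. Of 12307 circRNA probes above background on both arrays, 46 were at least 2-fold higher and 28 at least 2-fold lower in the knockdown, together 0.60%. The circRNA of probe ASCRP3001278 was 3.24-fold higher in the knockdown, with signals of 145 and 62.6 and a log2 ratio of 1.70 (scanner error 0.21). That of probe ASCRP3008134 was 2.96-fold higher, with a log2 ratio of 1.57 (scanner error 0.22), but fell short of 2-fold in the deposited values (0.96) and after normexp with an offset of 50 (0.78). The lowest relative to control was the circRNA of probe ASCRP3000387, 4.03-fold lower with signals of 25.7 and 145 and a log2 ratio of -2.01 (scanner error 0.21). Its log2 ratio was smaller in size in the deposited values (-1.57) and after normexp with an offset of 50 (-1.01). The circRNA of probe ASCRP3003391 was 3.80-fold lower, with a log2 ratio of -1.92 (scanner error 0.33), but its knockdown signal of 5.87 lay close to background and its log2 ratio was -0.46 in the deposited values and 0.05 after normexp. The 12 highest circRNAs spanned 2.37-fold to 3.24-fold, and the 12 lowest 2.45-fold to 4.03-fold. In the deposited values 3 of the former and 5 of the latter were at least 2-fold apart. Those counts partly follow signal level, since the added constant shrinks dim ratios most.

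The balance between higher and lower circRNAs depended on the scaling and the background correction. It was 46 higher against 28 lower with the 75th percentile of all circRNA probes. It was 30 against 45 after quantile normalization, 31 against 40 with the median of detected probes, 30 against 47 after loess, 4 against 5 after normexp with an offset of 50, and 3 against 342 with no scaling, which left the median log2 ratio at -0.44. Higher circRNAs still outnumbered lower ones, 41 against 30, with the 75th percentile of detected probes. They also did so at 30 against 16 with the median signal less local background. After subtracting the median of each array region it was 42 against 30. No direction therefore predominated across settings. In the authors' deposited values 11 circRNAs were at least 2-fold higher and 8 lower, and 16 of the 74 circRNAs were at least 2-fold apart there in the same direction. The constant added there, and in normexp with an offset of 50, shrinks dim ratios. Fewer dim circRNAs can reach 2-fold by construction, so the lower counts do not weigh against them. A core of 15 circRNAs, 7 higher and 8 lower, was at least 2-fold apart in the same direction under the main scaling, the 4 other scalings by quantile, percentile of detected probes, median and loess, and the deposited values. The percentile of detected probes and the median differ from the main scaling by a constant only. The deposited values alone kept 16, so the other scalings narrowed the core little further. The core had geometric mean signals of 49.8 or more, so it is partly a selection for bright probes. These settings were picked after the counts had been seen; 8 of the 15 were also 2-fold apart after normexp with an offset of 50, and 9 with no scaling.

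**Figure D1:**
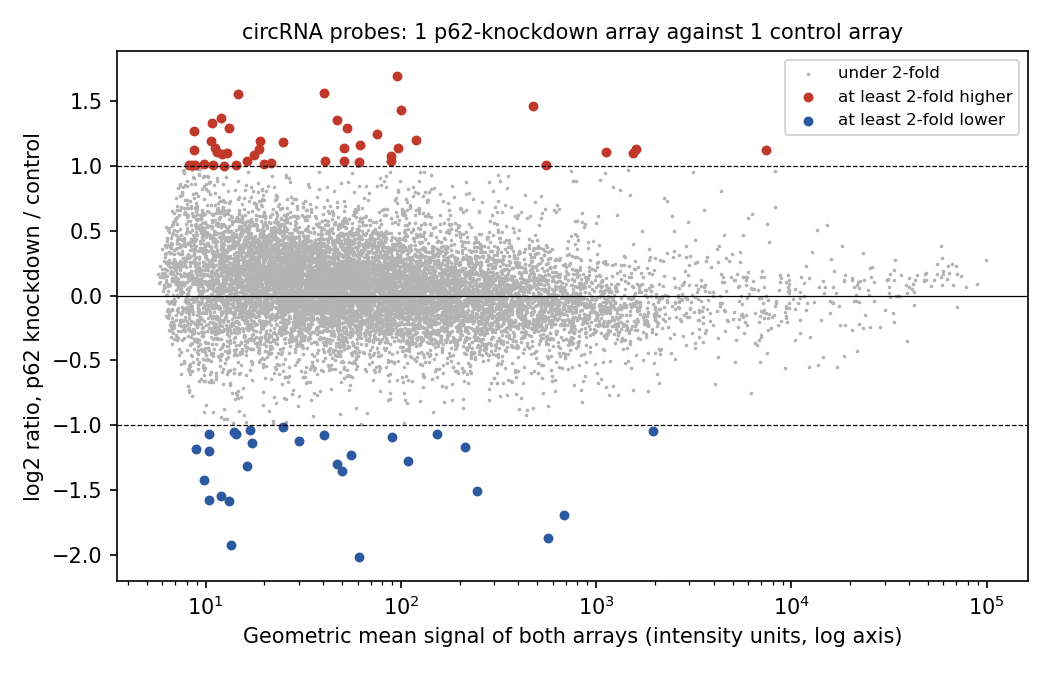
Log2 ratio of p62 knockdown to control for each of 12307 circRNA probes, against the geometric mean signal of both arrays on a log axis. Each point is 1 probe, the dashed lines mark 2-fold, and the 46 higher and 28 lower probes are coloured.

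Across these probes the log2 signals of both arrays correlated with r = 0.991, a correlation across probes, which are not independent replicates. The central 95% of log2 ratios ran from -0.53 to 0.66, and 67.2% of the circRNAs lay within 1.2-fold. Of the 100 brightest circRNA probes of each array 96 were shared, and the 6 brightest had log2 ratios of -0.09 to 0.27. Of the 74 circRNAs at least 2-fold apart, 24 had a mean level above the median of the probes compared, 15 of them higher and 9 lower. Among circRNAs with a signal over 100, the SD of the log2 ratio was 0.269, against 0.074 between replicate spots of the same probe. In the lowest range, under 10, these were 0.373 and 0.356. The spot SD does not cover all that separates probes. Between the 15 circRNA control probes, each averaged over its spots, the SD was 0.245, with 1 probe at 0.76. That SD is close to the spread between the brighter circRNAs, but it rests largely on this probe, since the others ran from -0.27 to 0.17. What these probes bind was not examined, so their SD does not set a technical floor for the circRNAs.

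**Figure D2:**
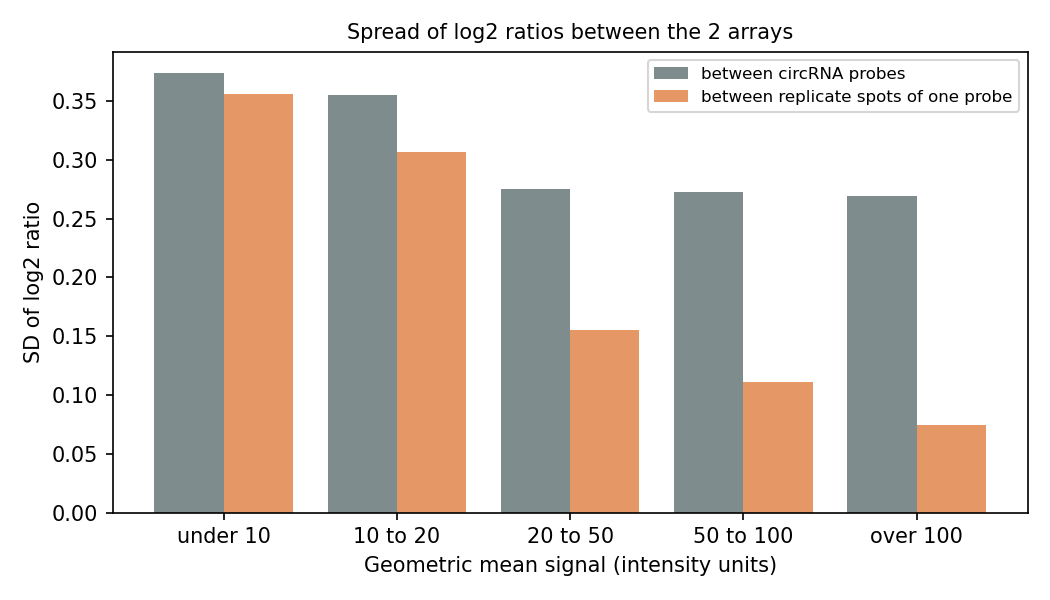
SD of the log2 ratio of p62 knockdown to control in 5 ranges of geometric mean signal, between circRNA probes and between replicate spots of the same probe. Above a signal of 100 the circRNA spread is 0.269 and the spot spread 0.074.

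Some circRNAs were well above background on 1 array only. There were 217 such probes in the knockdown, 10 of which had a bound of at least 2-fold, and the 4 largest were at least 2.22-fold. There were 165 in the control, 17 of which had a bound of at least 2-fold, and the 4 largest were at least 3.56-fold. Each bound sets the brighter signal against the higher of the dim probe's own signal and the lowest signal well above background on its array. With the scanner's less strict detection flag the numbers were 117 in the knockdown and 78 in the control, of which 56 and 34 had a bound of at least 2-fold, so which sample had more probes with such a bound turned with the flag.

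Named genes were measured by 70 mRNA probes with 10 spots each, on RNA from which linear RNA had been digested with RNase R. Whether they read leftover linear RNA or circular RNA of the same gene is not given in the sources used here, and the values below are probe signals in that sense. Of these, 61 were measured on both arrays, none differed by 2-fold, and 40 had positive and 21 negative log2 ratios. MOCOS, which encodes molybdenum cofactor sulfurase, stood lowest: its signal was 1.62-fold lower in the knockdown, with a log2 ratio of -0.70 ± 0.036 (SE over 9 spots). ITGB3BP, which encodes a centromere protein, was highest, with a log2 ratio of 0.58 ± 0.033 (SE over 10 spots). EXO1, a DNA repair exonuclease, had a log2 ratio of 0.52 ± 0.054. Both kept a positive log2 ratio in all settings run, and MOCOS a negative one. The SE covers spots within an array, not cultures, and these genes were named after their values were seen. The rule for a measured probe was also passed by 30 of the 60 negative control probes. These had signals up to 160 in the knockdown and 220 in the control, and log2 ratios of -0.23 to 0.79. Passing the rule therefore does not show that a signal comes from the named gene. The log2 ratios of ITGB3BP and EXO1 lay inside that range. Their signals were also below the highest of those probes, at 111 and 104 for ITGB3BP and 20.1 and 19.6 for EXO1.

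Genes of mitosis and DNA replication, a list drawn up after the panel was seen, had log2 ratios of both signs: 12 of 18 measured were positive and 6 negative, against 40 and 21 in the whole panel. SPDL1, a spindle checkpoint adaptor, had a log2 ratio of 0.41 ± 0.025, and the mitotic regulator PIMREG one of 0.26 ± 0.012. WDHD1, a replication fork protein, had a log2 ratio of -0.33 ± 0.033, and the kinetochore motor CENPE one of -0.14 ± 0.015. Genes often used as references also had both signs: ACTB, which encodes beta-actin, had a log2 ratio of 0.41 ± 0.045, whereas GAPDH, a glycolytic enzyme, had one of -0.22 ± 0.021. The ribosomal protein genes RPLP1 and RPS18 had log2 ratios of -0.34 ± 0.021 and 0.20 ± 0.018. CPS1, a urea cycle enzyme, had a log2 ratio of -0.29 ± 0.043 and SERPIND1, which encodes heparin cofactor II, one of -0.27 ± 0.019. With no scaling the positive log2 ratios of SPDL1, PIMREG, ACTB and RPS18 turned negative, along with the whole median. The negative ones named here stayed negative in all settings run. Apart from PIMREG and SERPIND1, these probes were dimmer than the brightest measured negative control probe, at 160 in the knockdown and 220 in the control. ACTB, for example, had signals of 36.2 and 38.0, and GAPDH 121 and 197. Whether such signals come from the named genes is therefore not known.

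**Figure D3:**
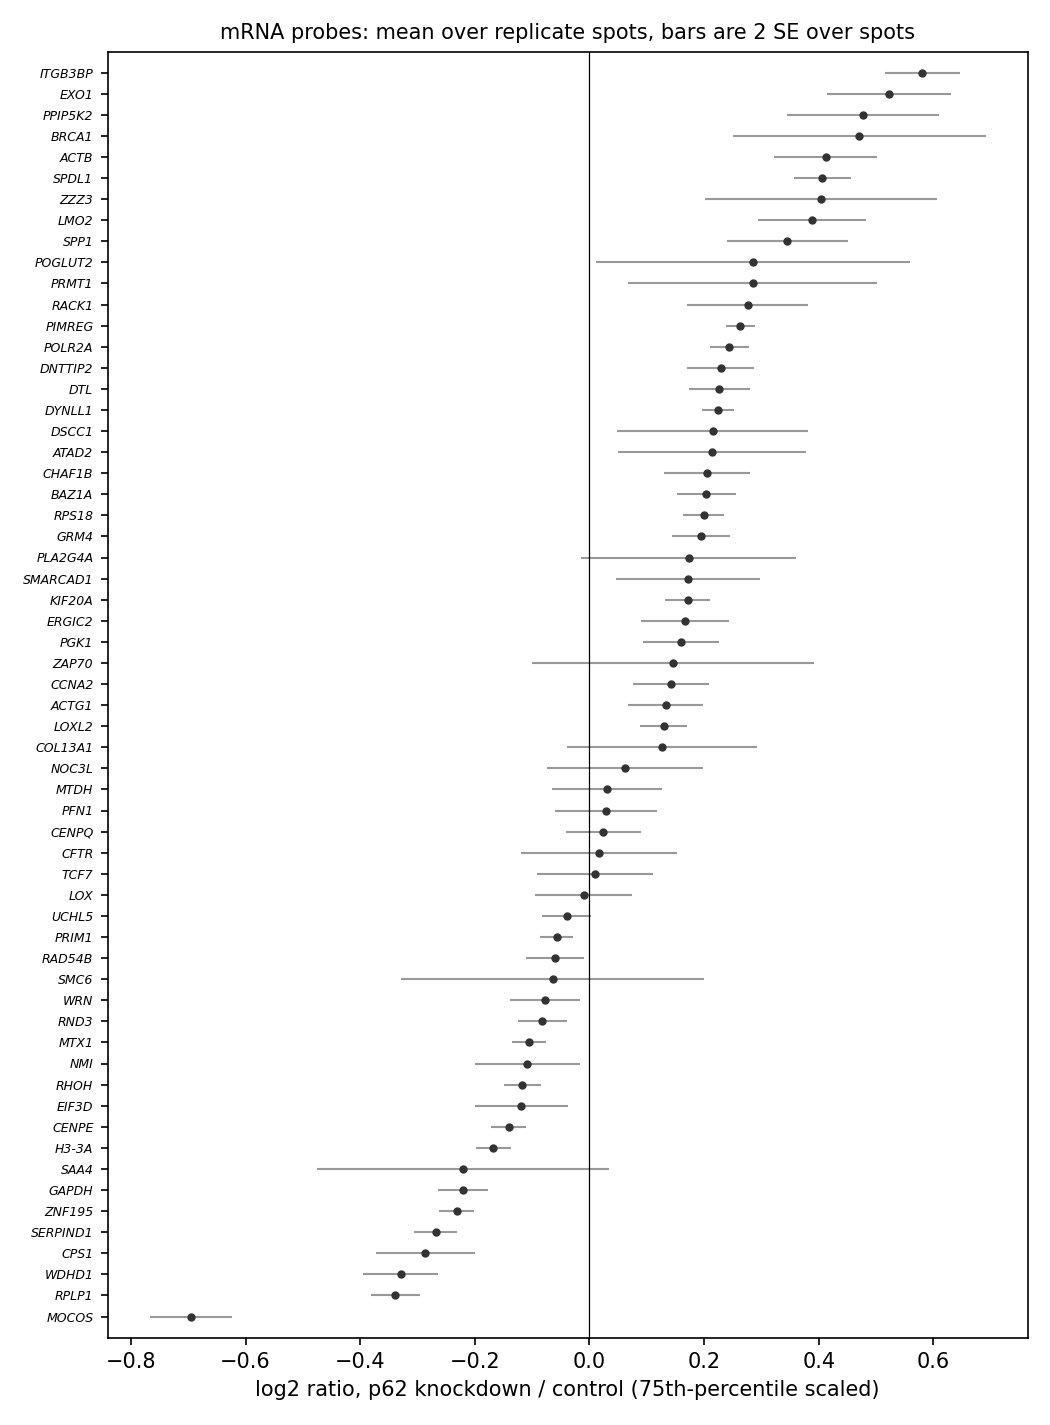
Log2 ratio of p62 knockdown to control for the measured mRNA probes, apart from 1 that is not reported here. Points are means over replicate spots and bars are 2 SE over spots; MOCOS lies at -0.70 and ITGB3BP at 0.58.

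Of the 18 gene lists fixed before the data were examined, 4 had a member among the mRNA probes, with 7 genes in all, and 14 had none, including p62 partners, autophagy machinery and monocyte genes. In the cell cycle list CCNA2, the cyclin of S phase and mitosis, had a log2 ratio of 0.14 ± 0.033, opposite to CENPE. In the chromatin list BAZ1A and SMARCAD1, both chromatin remodelling factors, had log2 ratios of 0.20 ± 0.026 and 0.17 ± 0.063. POLR2A, the largest subunit of RNA polymerase II and a host gene of a circRNA, had one of 0.24 ± 0.017. The lymphoid markers ZAP70 and TCF7 had log2 ratios of 0.15 ± 0.12 and 0.01 ± 0.051, both within 2 SE of 0. All of these turned negative with no scaling except CENPE, which was negative throughout. SMARCAD1 turned negative in the rebuilt deposited values, ZAP70 after loess, and TCF7 under several scalings. Apart from POLR2A, with signals of 2936 and 3471, these probes were also dimmer than the brightest measured negative control probe.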

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

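All tests in this part were chosen after the result was seen, and the predictions they were set against were written afterwards too. The spot noise was first simulated, and replicate spots were compared after that: with outlier spots kept, simulated noise alone gave a median of 15 and at most 23 circRNAs at 2-fold in 100 simulations, against 74 seen. The simulation with planted changes counted more, 30 of 12107 unchanged circRNAs. Why these simulations differ was not examined, so the number expected from noise is uncertain.

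A negative control probe, Negative008, was brighter on the knockdown array, with a log2 ratio of 1.354 (2.56-fold; SE over spots 0.042) and mean signals of 191 and 104. It lies in data outside the comparison. It was picked for the largest ratio among 32 negative control probes whose unflagged spots were all well above background on both arrays. A local speck on the array was tested: 10 of 10 knockdown spots, outlier spots included, lay above the highest control spot, which argues against it. It stayed 1.83-fold brighter with no scaling. Since 3 of its 10 spots were marked as outliers, and it was picked for its ratio from 32 of the 60 such probes, it may be a chance extreme. RNA that binds this probe may also differ, and no biological explanation was tested.

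The 74 circRNAs at least 2-fold apart were set against 3 technical explanations. For spot-to-spot noise, brighter and dimmer circRNAs were judged by different rules. For the 38 with signals of 20 or more, the largest deviation among 789 replicate spots was 0.575 on the log2 scale. By the rule on the largest deviation this argues against ordinary spot noise. By the exact bound used for dimmer signals it stays open. Rare defective spots at up to 0.466% could give the 0.386% seen. For the 36 with signals under 20 spot noise stays open. There 0.885% of 339 spots lay 2-fold from their own probe (exact 95% interval 0.183% to 2.56%) against 1.46%. The signal was already spatially detrended by the scanner software, so only a regional trend left after that could be tested, across 32 regions. It is argued against less firmly, since 90.54% stayed at least 2-fold apart once region medians were subtracted, only just over the 90% asked for. These medians ran from -0.02 to 0.12. Defects smaller than a region are not covered. Spots near background cannot be told apart from a difference in RNA for the dimmer circRNAs, as 32.43% lay above the median level of the probes compared, between the bounds set. Differences in culture, RNA digestion or labelling, and p62 knockdown itself, stay open with 1 array per group.

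More circRNAs were higher than lower in the knockdown at 1.5-fold, 487 against 220 (68.9% higher). The share of higher circRNAs does not separate a level-dependent shift between the arrays from a constant offset. Under loess 47.53% were higher, but the median of detected probes, which shifts every probe alike, gave 49.0% as well. The median log2 ratio did fall with signal: 0.15 under 10, 0.14 at 10 to 20, 0.09 at 20 to 50, 0.07 at 50 to 100 and -0.02 over 100. This argues against a constant offset alone, which would give the same median in each range. How much of the excess at 1.5-fold comes from the trend is not decided. No biological explanation was tested for this pattern.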

How the results depend on the processing

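The settings called added here were chosen after seeing the data. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. The numbers of circRNAs at least 2-fold higher and lower, 46 and 28, moved to 30 and 45 after quantile normalization, 30 and 47 after loess, 3 and 342 with no scaling, and 30 and 16 with the median signal less local background. They moved to 4 and 5 after normexp with an offset of 50 (added), and to 11 and 8 both in the deposited value table and in its rebuilt form (added). All of these add a constant to every signal, which lowers the counts of dim circRNAs by construction. Filters and size rules moved them as built: 111 and 74 with background passed on at least 1 array, 18 and 11 above the median level of all circRNA probes, 233 and 141 with no filter, 487 and 220 at 1.5-fold, and 0 and 1 at 4-fold. They were 41 and 30 with the 75th percentile of detected probes, 31 and 40 with the median of detected probes, and 42 and 30 after subtracting region medians (added). Leaving out saturated probes moved nothing, as none was saturated. The circRNAs above background on 1 array only moved from 217 to 117 and from 165 to 78 with the less strict flag.

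Of the 24 named circRNAs under 8 settings, 144 values stayed within the 95% range of the scanner error around the main one, 44 moved and 4 changed sign. All 4 that changed sign were lower circRNAs with dim knockdown signals, under normexp with an offset of 50, with log2 ratios of 0.0519, 0.0787, 0.1939 and 0.117. That offset shrinks ratios at such signals, and the median log2 ratio of all compared probes was itself 0.14 in this setting. The sign changes therefore do not bear on the direction of these circRNAs. Whether anything else contributed was not tested. Of the 61 mRNA probes, 43 kept their sign under the 8 settings other than no scaling, which changed 38. The looser spot rule (added) measured 64 probes, with 41 positive and 23 negative. Alternatives on host genes, gene list medians, classes and chromosomes were not run, for want of a pairing of probes with genes. Dim signals limit precision: the SD between replicate spots was 0.356 at signals under 10 and 0.074 over 100.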

Other observations

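All tests in this part were chosen after the result was seen.

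Among genes not yet described, the haematopoietic transcription cofactor LMO2 had a log2 ratio of 0.39 ± 0.047 (SE over 10 spots) and SPP1, which encodes osteopontin, one of 0.35 ± 0.053. Both turned negative with no scaling. Their signals, 13.4 and 14.3 for LMO2 and 40.6 and 44.7 for SPP1, lay below the brightest measured negative control probe. DYNLL1, a dynein light chain, had one of 0.22 ± 0.014, also negative with no scaling, and the histone gene H3-3A one of -0.17 ± 0.015, negative in all settings run.

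The 15 circRNA control probes had a median log2 ratio of -0.01. AS_circRNA_control207 had one of 0.76, and the others ran from -0.27 to 0.17. Of the 60 negative control probes 30 were measured, with a median log2 ratio of 0.16 and a range of -0.23 to 0.79.

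One hypothesis was that linear RNA was removed unequally from the samples, which would shift mRNA probes against circRNA probes if the former read leftover linear RNA. The median of the 61 mRNA probes, 0.14, lay at percentile 98.91 of matched random circRNA lists, but this depended on the processing: of the 5 other settings that can change the rank, 1 put it outside the central 95%, at 98.6 with the median signal less local background, and 4 inside, at percentiles 93.6 after quantile normalization, 85.7 after loess, 63.0 after normexp and 71.4 in the rebuilt values. With the looser spot rule it lay at 98.01. The measured negative control probes had a median as high, 0.16, but were not matched on level. The circRNA probes themselves had medians of 0.15 at signals under 10 and 0.14 at 10 to 20. The negative control median therefore does not bear on the cause. Since the rank of the mRNA probes depended on the processing, their shift may come from it, and these arrays do not decide it.

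Another was that replication and mitosis genes shifted together within the mRNA panel. Their median, 0.19 over 18 measured genes with 12 positive and 6 negative, lay at percentile 90.18 of random lists from the panel, within the central 95%, which leaves a small common shift open.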
